A study of Mus musculus with 40 samples.

How the data were processed

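Liver RNA was sequenced from 40 male C57BL/6 mice housed at 28 °C. Per the labels, the mice were 30 days old at the start and 58 days at the end, acclimated for 5 days, and received 0.1 mL of sesame oil or of TCDD in sesame oil by gavage every 4 days over 28 days, 7 gavages in all. The labels give 8 groups of 5 mice, vehicle and 0.03, 0.1, 0.3, 1, 3, 10 and 30 µg/kg. Replicate numbers were given here in order and only name a library. Per the labels' protocols the RNA had an integrity number of at least 7, libraries were made with the NEBNext Ultra II kit, and both ends of each fragment were read for 150 bases.

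The files were 40 tables of deposited counts per gene, 1 for each library, and 1 deposited table of normalized values on a log2 scale. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.39 and STAR 2.7.3a were used. The notes also name the builds GRCm39 and mm10 without a role, so the build behind the counts is not given in the sources used here. The deposited counts covered 55359 gene identifiers, of which 52083 had a symbol in GENCODE M21 and 3276 had none. The coordinates in the report come from GENCODE M21 on GRCm38 and were matched by gene identifier. The 2 stranded count columns differed by a ratio of 1.005 to 1.014 in every library, less than the 3 needed by the rule for a stranded column, so the unstranded column was used, and reads of overlapping or antisense genes could not be told apart. The deposited normalized table held log2 values of 23835 genes between 4.808 and 20.757, with the same lowest value in all 40 columns. Its transformation and filter are not given in the sources used here. A setting chosen in advance called for the log2 of its values plus 1. Since the table was already on a log2 scale, it was used as deposited.

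Counts in genes lay between 15311574 and 29476550 per library, with a median of 19090070.5. The 4 summary lines of each count table name no gene and stayed out of library sizes and tests. They held between 2.25% and 31.7% unmapped reads, 4.46% to 6.79% multimapping reads, 3.65% to 9.37% reads in no gene and 3.59% to 5.73% ambiguous reads. Intervals of these shares are 95% Wilson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules. No 2 libraries of a group held identical counts. The lowest chi-square per gene between 2 libraries of a group, over genes with a summed count of at least 20, was 8.81, where sampling alone gives about 1, so each library counted as 1 replicate.

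Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling and filterByExpr. All 40 libraries entered 1 fit with 1 coefficient per group, so that the groups shared 1 estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15610 genes tested. The same fit gave each dose against vehicle, 10 against 3 µg/kg, 30 against 10 µg/kg and a test of any difference between the 8 groups. A trend used the dose rank as 1 numeric term over all 40 libraries and, as an alternative, over the 35 libraries labelled with a TCDD dose (15280 genes tested). Log2 fold changes and slopes are given with their standard errors.

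The tests, the gene lists, the rule for named genes and the other settings, except those given as added later, were chosen before the data were examined. Of 45 lists of pathways and cell types, 43 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation between genes, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. The tests of lists for the trend over libraries labelled with TCDD were added after the data were seen. Some lists share members, such as Slco1a1, which is in the male-biased and bile acid transport lists. Results of some single genes are not reported here.

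The rule for named genes takes, at every dose, Cyp1a1, Cyp1a2, Cyp1b1, Tiparp, Ahrr, Nqo1 and Ahr. At 30 µg/kg against vehicle it takes the 10 largest rises and 10 largest falls among called protein-coding genes with a symbol, a mean of at least 1 CPM in the higher group and no overlap of values. At each lower dose, and for 30 against 10 µg/kg, it takes the 3 largest of each. In each list with a called member at 30 µg/kg it takes up to 4 called members with the smallest adjusted p. Genes named from the trend without vehicle fall outside this rule. They were chosen from the lists after the values were seen.

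The other settings were DESeq2 size factors, upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of 1 CPM in 5 libraries, fits of only the 2 groups compared, the 2 runs of title numbers as a covariate, a minimum log2 fold change of 1, limma on the normalized table, the trend without vehicle, and refits leaving out each library in turn. The unstranded column was already in use, so that alternative did not apply. After the AhR genes had been seen in each library, further fits were added: without vehicle replicates 4 and 5, and with only 24 libraries. The 24 are those whose labelled dose is in step with a layout of the title numbers in runs of 3 per dose. That layout was inferred after the values were seen and is stated by no label. No library was given another dose, and the AhR genes in these fits are not independent evidence.

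The tests were run on simulated counts with 200 changed genes, 100 of them by 2-fold and 100 by 4-fold, drawn from the means, spreads and library sizes of these libraries. In the fit of 30 µg/kg against vehicle with 40 libraries (15280 genes), edgeR recovered 74% of the 2-fold and 96% of the 4-fold changes with 10 false calls. On the same counts limma-voom recovered 71% and 94% with 11 false calls, DESeq2 78% and 98% with 22, and camera called the changed list and 0 of 100 unchanged lists. Each gene was drawn independently and the unchanged lists were random. The simulation thus gives no measure of false list calls where the genes of a list vary together. Every simulated library also followed its label. The recovery and false calls of genes thus do not cover labels that the AhR genes go against, as in vehicle. For the trend without vehicle (15201 genes), with changes of these sizes spread over the whole dose range, edgeR recovered 77% and 97% with 8 false calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The labels name separate mice, so p-values of the comparisons of groups measure the spread between mice with the same label. Where the AhR genes split the libraries of a label, as in vehicle, this spread includes that difference. P-values and standard errors of the trends measure the scatter of the libraries around a straight line over dose rank. That scatter also includes any departure of the group means from the line.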

Results

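The data describe how gene expression in the liver of mice housed at a thermoneutral 28 °C changed with the dose of the dioxin TCDD, a persistent ligand of the aryl hydrocarbon receptor (AhR). Male C57BL/6 mice, an inbred laboratory strain, received 7 oral gavages at intervals of 4 days. The labels give 8 groups of 5 mice each: sesame oil vehicle, and TCDD at 0.03, 0.1, 0.3, 1, 3, 10 and 30 µg/kg. The 40 liver RNA-seq libraries held between 15311574 and 29476550 counts in genes (median 19090070.5). Levels are given below as TMM-scaled CPM (counts scaled to a common library size), as mean ± SD of the 5 libraries with the same label.

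Genes known to be induced through AhR were compared first in every library, because they check the labels. Cyp1a1, a xenobiotic-metabolising enzyme and the usual readout of AhR activity, lay at 1.19, 2.12 and 1.30 CPM in the libraries labelled vehicle replicates 1, 2 and 3. It lay at 6786 and 6828 CPM in the libraries labelled vehicle replicates 4 and 5, within the range of the 5 libraries labelled 30 µg/kg (4818 to 9214 CPM). Cyp1b1 lay at 2257 and 1911 CPM in these 2 libraries, above each library labelled 30 µg/kg (514 to 1390 CPM), and between 0.156 and 0.956 CPM in the other 3. Nqo1 lay at 233 and 171 CPM in them, against 38.4 to 88.1 CPM in the 5 labelled 30 µg/kg. The albumin gene Alb lay at 35725 and 45718 CPM in them, against 81190 to 88723 CPM in the other 3 labelled vehicle. In the libraries labelled 0.03 µg/kg replicates 3 and 4 Cyp1a1 lay at 1.27 and 2.28 CPM, against 214 to 266 CPM in the other 3 of that label. Other labels were split too. Cyp1a1 lay at 215 and 209 CPM in 0.1 µg/kg replicates 3 and 4 (1066 to 1699 in the others). It lay at 1404 and 1692 CPM in 0.3 µg/kg replicates 1 and 3 (3265 to 4491). Cyp1b1 in replicates 1 and 2 lay at 6.66 and 7.4 CPM at 1 µg/kg (85.1 to 117). It lay at 87.2 and 108 CPM at 3 µg/kg (249 to 257) and 172 and 155 CPM at 10 µg/kg (497 to 570). In 30 µg/kg replicate 2 it lay at 514 CPM (1111 to 1390). The AhR genes thus go against the labels of at least the 2 vehicle libraries and split those of each dose. Every library kept its label, and each direction against vehicle given below is a direction against the libraries labelled vehicle.

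**Figure D1:**
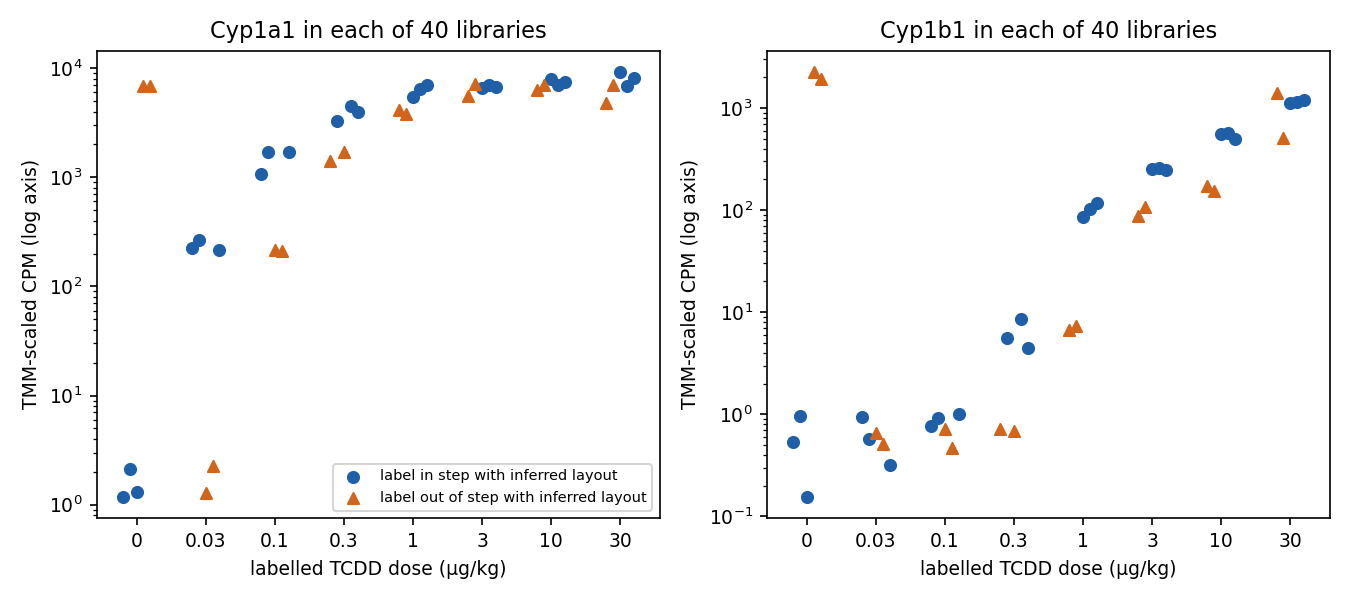
Cyp1a1 and Cyp1b1 in each of the 40 libraries (TMM-scaled CPM, log axis) against the labelled TCDD dose in µg/kg; triangles mark 16 libraries whose label is out of step with a layout of the title numbers that was inferred after these values were seen and that no label states. The libraries labelled vehicle replicates 4 and 5 lie at 6786 and 6828 CPM of Cyp1a1, the other 3 of that label between 1.19 and 2.12 CPM.

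By the GENCODE M21 annotation of GRCm38, Cyp1a1 (ENSMUSG00000032315) lies on chromosome 9 from 57687928 to 57703824, and Cyp1a2 (ENSMUSG00000032310) on chromosome 9 from 57676937 to 57683703. Cyp1b1 (ENSMUSG00000024087) lies on chromosome 17 from 79701537 to 79715061, Tiparp (ENSMUSG00000034640) on chromosome 3 from 65528410 to 65555518, and Ahrr (ENSMUSG00000021575) on chromosome 13 from 74211118 to 74292331. Nqo1 (ENSMUSG00000003849) lies on chromosome 8 from 107388225 to 107403206, and Ahr (ENSMUSG00000019256) on chromosome 12 from 35497974 to 35535038.

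Among the 35 libraries labelled with a TCDD dose, the AhR target genes named here had a positive slope over dose rank, though not a higher mean at each dose: Tiparp lay at 4.50, 4.62 and 4.40 CPM at 0.03, 0.1 and 0.3 µg/kg and at 116 CPM at 30 µg/kg. Cyp1b1 rose by 1.95 ± 0.13 (SE) on the log2 scale per dose step, from 0.600 ± 0.232 CPM at 0.03 µg/kg to 1067 ± 328 CPM at 30 µg/kg (edgeR adjusted p = 2.54e-15). Ahrr, which encodes the AhR repressor, rose by 1.501 ± 0.11 per step and Tiparp, an ADP-ribosyltransferase, by 0.84 ± 0.06. Cyp1a1 rose by 0.78 ± 0.15, Cyp1a2 by 0.51 ± 0.05 and Nqo1, a quinone reductase, by 0.47 ± 0.03, while Ahr itself rose by 0.07 ± 0.02 (edgeR adjusted p = 0.0135). In the AhR battery list 12 of 14 tested genes rose and 0 fell (camera adjusted p = 3e-11, and adjusted p = 0.0289 with an estimated correlation). Over all genes 3592 rose and 3225 fell, 6817 of the 15280 tested. The genes named from this trend were taken from the fixed lists after its result was seen. The trend without vehicle was planned as an alternative, and emphasis was moved to it after the label conflict had been seen. Its libraries include 14 whose labels are out of step with the inferred layout; without them 5828 genes were called, of which 5243 were also called in all 35, and Ahr rose by 0.11 per step.

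Genes of detoxification and genes with a sex difference in mouse liver changed with dose in the same libraries. Of 15 NRF2 targets, which respond to oxidative stress, 9 rose and 0 fell, among them Nqo1 and the glutathione peroxidase gene Gpx2 (camera adjusted p = 3.66e-05, and adjusted p = 0.12 with an estimated correlation). Gpx2 rose by 1.75 ± 0.11 per step, a slope that depends on counts near 0, since 1 library of 5 held a count of it at each of 0.03, 0.1 and 0.3 µg/kg. Of 15 male-biased liver genes 10 fell and 0 rose (camera adjusted p = 3.38e-06, and adjusted p = 0.297 with an estimated correlation). Hsd3b5, a male-specific steroid dehydrogenase, went from 198 ± 41.7 CPM at 0.03 µg/kg to 0.200 ± 0.422 CPM at 30 µg/kg, and Serpina1e, a protease inhibitor, from 5773 ± 1434 to 152.5 ± 311.8 CPM. Replicate 2 set both means at 30 µg/kg, with Hsd3b5 at 0.954 CPM (at most 0.048 in the other 4) and Serpina1e at 710.2 CPM (6.55 to 18.6 in the other 4). Of 15 female-biased liver genes 10 rose and 1 fell (camera adjusted p = 0.00032, and adjusted p = 0.275 with an estimated correlation), and in the 21 libraries in step edgeR called 0 falling (0 at an unadjusted p under 0.05). Serpina1, Mup and Saa genes belong to families of near-identical copies, so the share of reads counted for each member is uncertain.

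**Figure D2:**
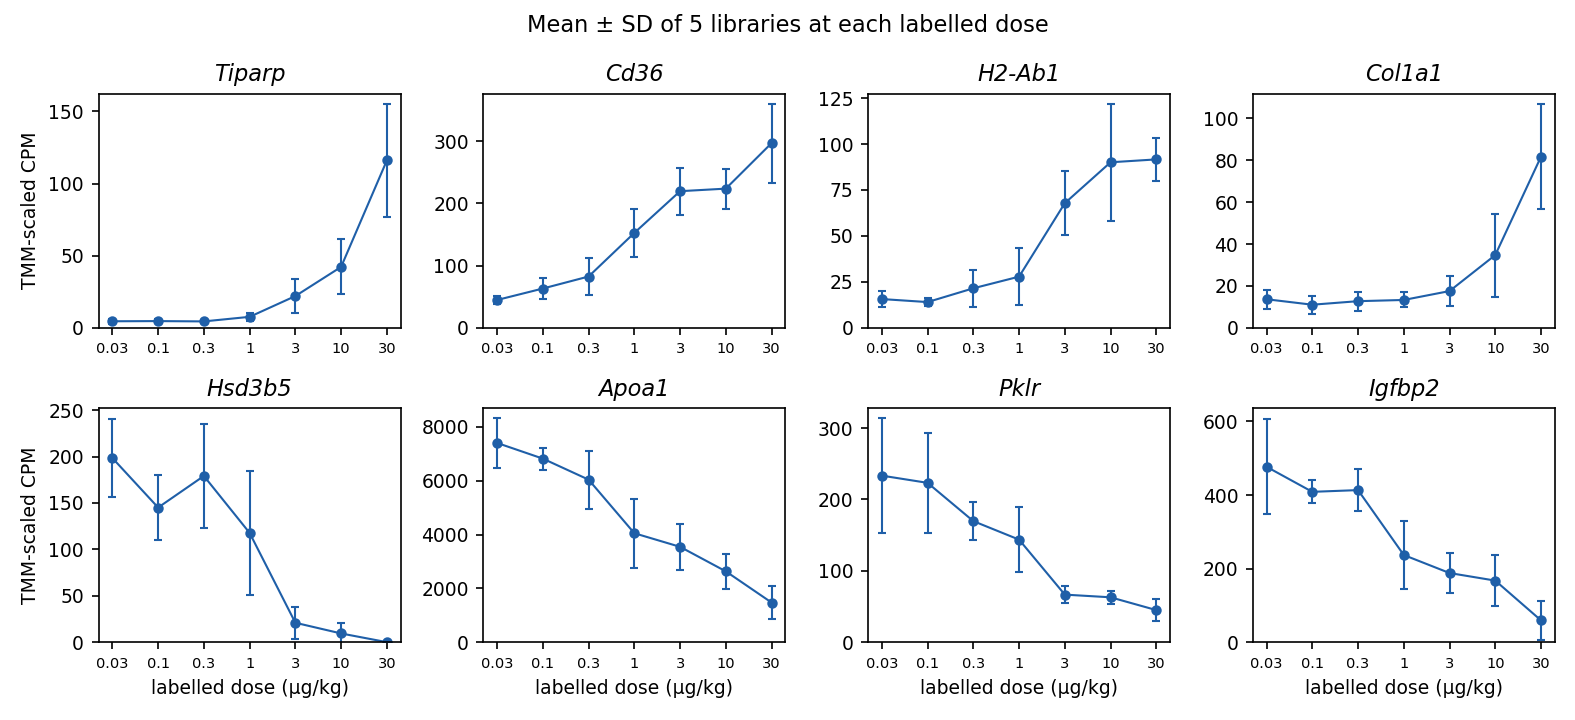
Levels of 8 genes (TMM-scaled CPM, mean and SD of the 5 libraries with each label) against the labelled TCDD dose in µg/kg. Over the 7 doses the slope per dose step was positive for Tiparp, Cd36, H2-Ab1 and Col1a1 and negative for Hsd3b5, Apoa1, Pklr and Igfbp2.

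Most called genes of lipid synthesis, lipid export and fatty acid oxidation fell with dose. In de novo lipogenesis 11 of 17 genes fell and 2 rose (camera adjusted p = 0.00304, and adjusted p = 0.443 with an estimated correlation). Mlxipl, which encodes the carbohydrate-responsive transcription factor ChREBP, fell from 676 ± 84.6 CPM at 0.03 µg/kg to 201 ± 73.4 CPM at 30 µg/kg, and the elongase gene Elovl5 rose from 830 ± 163.5 to 1624 ± 428 CPM. In lipoprotein assembly 8 of 11 fell and 1 rose (camera adjusted p = 0.00531, and adjusted p = 0.275 with an estimated correlation), and in the 21 libraries in step 2 rose. Apoa1, the main protein of high-density lipoprotein, fell from 7401 ± 922 to 1477 ± 607 CPM, and Apoe fell by 0.14 on the log2 scale per step. In fatty acid oxidation 12 of 25 fell and 1 rose, with Etfdh and Cpt2 falling (camera adjusted p = 0.0025, and adjusted p = 0.56 with an estimated correlation). The list of lipid uptake and droplets was not called, with 6 of 15 rising and 6 falling (camera adjusted p = 0.603, direction up with a median of -0.05; 6 rising and 8 falling adjusted over the list alone). In it the fatty acid transporter gene Cd36 rose from 44.6 ± 6.45 to 296.6 ± 63.6 CPM.

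Lists of other hepatocyte functions were called down with dose. In complement and coagulation 14 of 20 genes fell and 1 rose, with F7 and C9 falling (camera adjusted p = 0.000356, and adjusted p = 0.297 with an estimated correlation). Of the glucose production and glycogen genes 6 of 14 fell, Gys2 (glycogen synthase) among them, and 1 rose, Fbp1 (camera adjusted p = 0.00584, and adjusted p = 0.375 with an estimated correlation). Of the urea cycle genes 3 of 7 fell, among them Otc, from 431 ± 33.3 to 127 ± 64.2 CPM, and Asl (camera adjusted p = 0.0491, and adjusted p = 0.509 with an estimated correlation). One-carbon and transsulfuration genes fell in 8 of 16 and rose in 3, with Cbs and Shmt1 falling (camera adjusted p = 0.0292, and adjusted p = 0.526 with an estimated correlation). Respiratory chain genes fell in 8 of 20 and rose in 0, with Cycs and Cox7a2 falling (camera adjusted p = 0.00971, and adjusted p = 0.59 with an estimated correlation), and in the 21 libraries in step 5 fell. The glycolysis list was not called, with 7 of 17 falling and 5 rising (camera adjusted p = 0.497); the pyruvate kinase gene Pklr fell from 233 ± 80.4 to 45.1 ± 15.5 CPM.

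Hepatocyte markers fell in 7 of 12 and rose in 0, Cebpa and Ambp among them (camera adjusted p = 0.00667, and adjusted p = 0.347 with an estimated correlation). Of 17 hepatokines and growth factors 8 fell and 4 rose (camera adjusted p = 0.0127, and adjusted p = 0.12 with an estimated correlation). Ahsg and Lect2 fell, and Igfbp2, which binds insulin-like growth factors, fell from 477 ± 129.5 to 59.6 ± 52.0 CPM. Of 13 bile acid synthesis genes 6 fell and 1 rose, with Baat and Scp2 falling (camera adjusted p = 0.0177, and adjusted p = 0.443 with an estimated correlation). In bile acid transport and FXR signalling 8 of 14 fell and 3 rose; the uptake carrier gene Slco1a1 fell and the export carrier gene Abcc4 rose (camera adjusted p = 0.0292, and adjusted p = 0.45 with an estimated correlation). Of 18 circadian clock genes 8 fell and 2 rose, with Arntl and Bhlhe40 falling (camera adjusted p = 0.0356, and adjusted p = 0.174 with an estimated correlation), and in the 21 libraries in step 1 rose.

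Markers of macrophages, stellate cells and endothelial cells rose with dose. Kupffer cell markers rose in 12 of 13, Cd68 and Csf1r among them (camera adjusted p = 5.77e-06, and adjusted p = 0.297 with an estimated correlation). In the library labelled 30 µg/kg replicate 1 these 13 markers lay above the mean of the other 4 of that label by a median of 2.08 on the log2 scale (1.49 to 5.64), with Csf1r at 404 CPM (64.6 to 91.6 in the others) and Cd68 at 40.9 CPM (9.18 to 14.8). Without that library 11 of the 13 rose, Csf1r by 0.26 per step in place of 0.37 and Cd68 by 0.23 in place of 0.30. Recruited macrophage and monocyte markers rose in 14 of 15 and fell in 1 (camera adjusted p = 0.000123, and adjusted p = 0.28 with an estimated correlation). The galectin gene Lgals3 rose by 0.57 ± 0.06 per step and the collagenase gene Mmp13 by 0.98 ± 0.11. Dendritic cell markers rose in 9 of 12, among them the antigen presentation genes Cd74, H2-Aa and H2-Ab1 (camera adjusted p = 0.000123, and adjusted p = 0.203 with an estimated correlation), and in the 21 libraries in step 5 rose. Stellate cell and fibroblast markers rose in 15 of 16, including Reln and the collagen gene Col1a1, from 13.6 ± 4.58 to 81.8 ± 25.2 CPM (camera adjusted p = 4.99e-07, and adjusted p = 0.275 with an estimated correlation). Sinusoidal endothelial cell markers rose in 11 of 13, Flt4 and Fcgr2b among them (camera adjusted p = 4.99e-07, and adjusted p = 0.12 with an estimated correlation). T and NK cell markers rose in 9 of 14 and fell in 1, with Il2rb and Gzmb rising (camera adjusted p = 0.00257, and adjusted p = 0.12 with an estimated correlation).

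Cell cycle genes rose in 21 of 24 and fell in 0 (camera adjusted p = 1.63e-06, and adjusted p = 0.28 with an estimated correlation). The replication licensing gene Mcm5 rose from 2.30 ± 0.792 CPM at 0.03 µg/kg to 12.4 ± 3.92 CPM at 30 µg/kg, and the cyclin gene Ccnb1 from 0.118 ± 0.0995 to 2.74 ± 1.83 CPM. Of 14 p53 targets 7 rose and 1 fell, with Ccng1 and Zmat3 rising (camera adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation). All 5 tested neutrophil markers rose (camera adjusted p = 0.00584, and adjusted p = 0.297 with an estimated correlation), and 8 of 9 B and plasma cell markers rose (camera adjusted p = 0.00584, and adjusted p = 0.275 with an estimated correlation). The library labelled 30 µg/kg replicate 1 set the size of several of these: without it S100a9 rose by 0.53 per step in place of 1.34, Mmp8 by 0.89 in place of 1.77 and Igkc by 0.13 in place of 0.43, while Ighm rose by 0.30 in place of 0.34. The acute phase list was not called (camera adjusted p = 0.414, direction down with a median of 0.06). In it 7 of 16 rose and 4 fell, without that library 1 rose and 7 fell, and in the 21 libraries in step 3 rose and 7 fell. Without that library the serum amyloid gene Saa1 had 0.04 per step (edgeR adjusted p = 0.684) in place of 0.96 (edgeR adjusted p = 6.03e-06).

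In all, 27 of 43 lists were called in this trend, and with an estimated correlation only 1, the AhR battery (camera adjusted p = 0.0289). Adjusted over the list alone, 11 NRF2, 11 female-biased, 16 stellate cell and 8 p53 genes rose, and 11 male-biased and 12 de novo lipogenesis genes fell. In the other called lists the count adjusted over the list alone differed by at most 1 gene. PPARalpha targets (5 of 15 rising, 7 falling), CAR and PXR targets (8 of 16 rising, 3 falling), cholesterol synthesis (2 of 24 rising, 6 falling) and the interferon response (8 of 18 rising, 4 falling) were not called. Neither were haem synthesis and iron (6 of 21 rising, 6 falling), ER stress and ATF4 (2 of 15 rising, 3 falling), heat shock and cold-inducible genes (3 of 13 rising, 2 falling) and cytosolic ribosomal proteins (1 of 20 rising). Among cell type markers those of pericentral hepatocytes (6 of 14 rising, 3 falling), periportal hepatocytes (2 of 14 rising, 5 falling), cholangiocytes (2 of 10 rising), erythroid cells (2 of 7 rising, 1 falling) and skeletal muscle and mesothelium (2 of 6 rising) were not called either (camera adjusted p between 0.157 and 0.888 for these 13 lists). With under 5 tested members, adipocyte markers (2 of 3 falling) and exocrine pancreas markers (1 of 1 rising) had no list test. Small counts moved when 1 library was left out. Without 30 µg/kg replicate 1 edgeR called 0 rising cholangiocyte markers (1 at an unadjusted p under 0.05), 1 rising erythroid, 1 rising adipocyte, 2 rising ribosomal protein and 5 falling ER stress genes. Cholangiocyte markers had 1 without 30 µg/kg replicate 3 or 4 or 0.03 µg/kg replicate 1, and erythroid markers 1 without 30 µg/kg replicate 2 or 4. Skeletal muscle and mesothelium markers had 1 without 30 µg/kg replicate 3, and ER stress 5 falling without 0.1 µg/kg replicate 1. Rising heat shock genes numbered 5 without 1 µg/kg replicate 1 or 10 µg/kg replicate 2 and 6 without 30 µg/kg replicate 2. Rising ribosomal protein genes numbered 2 without 0.03 µg/kg replicate 2 and 0 by edgeR without 0.03 µg/kg replicate 1 or 3 or 10 µg/kg replicate 4 (1 at an unadjusted p under 0.05 in each). In the called lists, counts of 0 or 1 against the main direction moved by 1 gene without single libraries: 21 of the 35 for fatty acid oxidation, 3 for lipoprotein assembly, 16 for female-biased genes, 8 for p53 targets, 6 for hepatocyte markers and 26 for the urea cycle. In the 21 libraries in step 1 erythroid marker rose and 1 ribosomal protein gene fell, and edgeR called 0 rising cholangiocyte markers and 0 rising ribosomal protein genes (0 of each at an unadjusted p under 0.05).

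**Figure D3:**
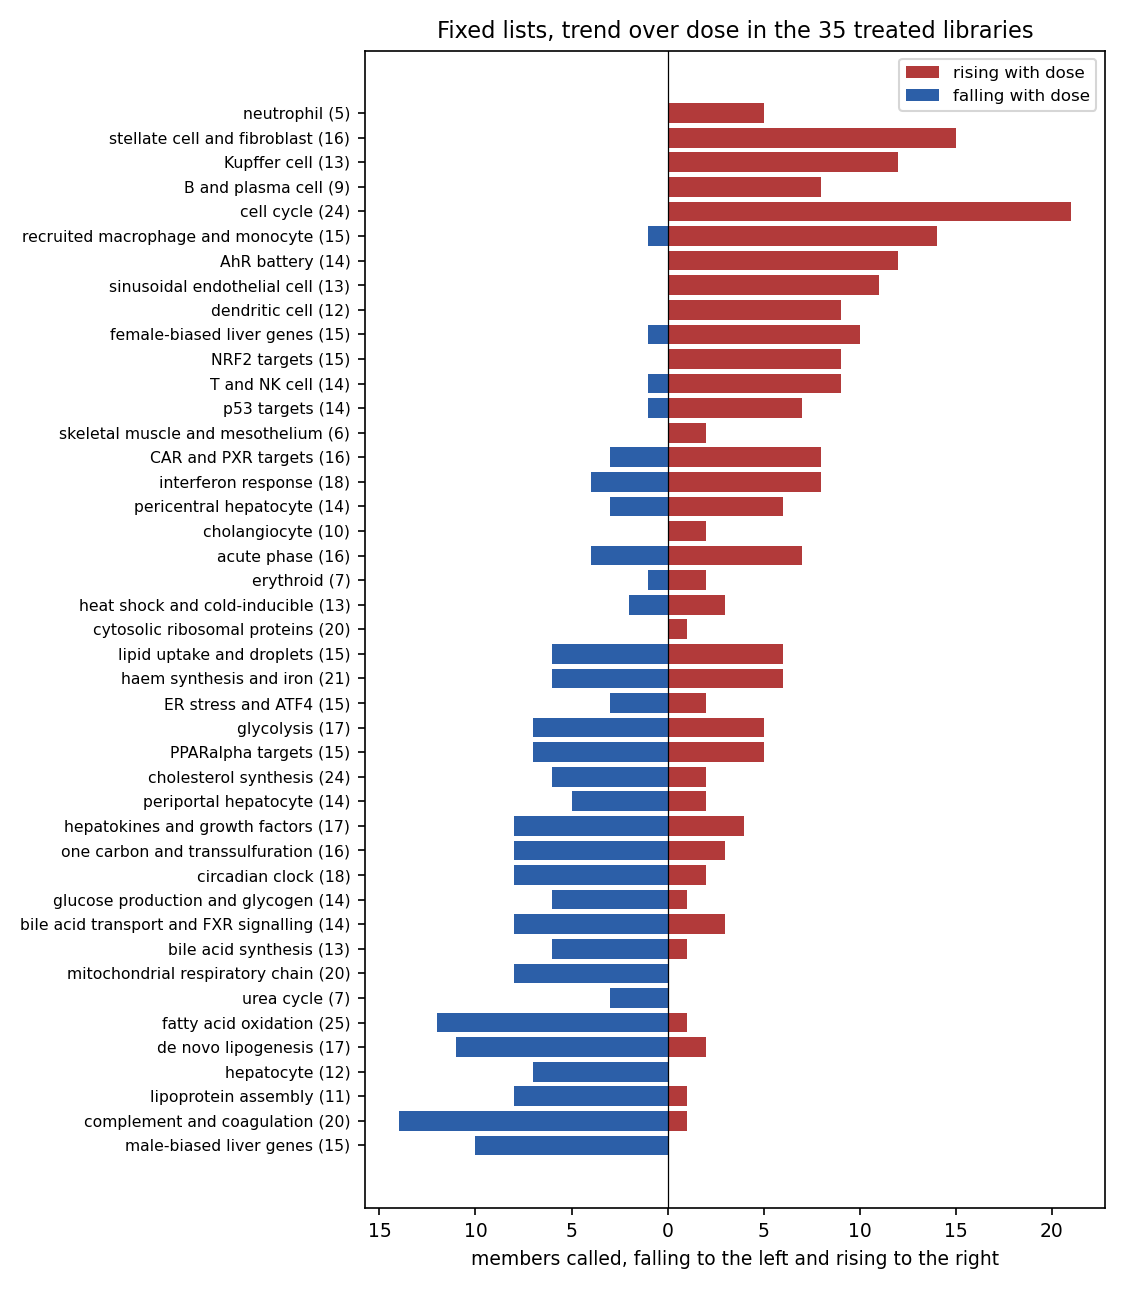
Members of each of the 43 tested lists called in the trend over the 35 libraries labelled with a TCDD dose; bars to the right count members that rose and bars to the left members that fell, with the number tested in brackets. In cell cycle 21 of 24 rose, and in complement and coagulation 14 of 20 fell.

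At 30 µg/kg 512 genes were higher and 450 lower than in the libraries labelled vehicle, 962 of 15610 tested. The largest rises among genes whose 5 and 5 values did not overlap were Smcp (log2 fold change 3.47 ± 0.86), the cytokine signalling inhibitor Socs1 (2.29 ± 0.56), Fndc9 (2.28 ± 0.62), the sulfotransferase Sult5a1 (2.02 ± 0.50) and Rassf4 (1.97 ± 0.40). Acpp, Trpm2, Atp2a3, the NK cell receptor gene Klrk1 and the purinergic receptor gene P2rx7 followed, down to 1.35 ± 0.39. The largest such falls were the chemokine gene Ccl21a (-3.22 ± 0.74), Csad, which acts in taurine synthesis (-1.62 ± 0.36), Grik5 (-1.41 ± 0.23) and Cyp3a59 (-1.39 ± 0.29), followed by Zfp750, Simc1, Ugp2, Bcl9l, D16Ertd472e and Txndc5, up to -0.78 ± 0.14. Smcp was near 0, at 3.74 CPM in 30 µg/kg replicate 3 and 0.396 to 1.07 CPM in the others of that label. A gene whose level in vehicle replicates 4 and 5 reached that at 30 µg/kg overlaps and cannot enter these rises. None of the 7 AhR genes fixed for every dose was called: Cyp1a1 had 1.40 ± 1.18 (edgeR adjusted p = 0.523), Cyp1b1 0.36 ± 1.06 (0.885), Tiparp 0.84 ± 0.61 (0.439), Ahrr 0.87 ± 0.82 (0.579), Cyp1a2 1.17 ± 0.58 (0.225), Nqo1 -0.46 ± 0.53 (0.663) and Ahr 0.46 ± 0.18 (0.105). Of the named genes called at this dose 29 were no longer called without 30 µg/kg replicate 1, Socs1 (1.79) and P2rx7 (0.92) among them, 26, 17 and 21 without vehicle replicates 1, 2 and 3, and 8 without each of 30 µg/kg replicates 3, 4 and 5. Without 30 µg/kg replicate 1 Rassf4 went from 1.97 to 0.99 (edgeR adjusted p = 0.0419) and Trpm2 from 1.74 to 1.05 (edgeR adjusted p = 0.0206). Without vehicle replicate 1, 2 or 3 P2rx7 (1.12 to 1.29), Fndc9 (1.97 to 2.07) and Klrk1 (1.35 to 1.40) were not called. Klrk1 was also not called without 30 µg/kg replicate 5 (1.38). Smcp was not called without 30 µg/kg replicate 3 (2.52) or vehicle replicate 1 or 3 (both 3.20). The count was 434, 535 and 417 without vehicle replicates 1, 2 and 3, and 2257 and 1943 without vehicle replicates 4 and 5. With sample quality weights, planned before the data were examined, limma-voom called 4519 genes, with Cyp1b1 at 10.19 and Tiparp at 4.31, and edgeR on these 2 groups alone called 0 (1473 at an unadjusted p under 0.05, and 1436 by DESeq2 in all groups).

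Endothelial and macrophage markers were the fixed lists with the most called members at 30 µg/kg. Sinusoidal endothelial cell markers were higher in 10 of 13, with Kdr, Stab1, Cdh5 and Flt4 between 0.54 and 0.99 (12 adjusted over the list alone; camera adjusted p = 3.82e-10, and adjusted p = 0.265 with an estimated correlation). Kupffer cell markers were higher in 10 of 13 (12 adjusted over the list alone; camera adjusted p = 3.72e-07, and adjusted p = 0.529 with an estimated correlation). Without the library labelled 30 µg/kg replicate 1 these named members were no longer called: Csf1r went from 1.64 to 0.75, Adgre1 from 1.89 to 0.98, Cd163 from 1.24 to 0.56 and Clec4f from 0.89 to 0.45. Clec4f was also not called without vehicle replicate 3 (0.78). Male-biased genes were lower in 5 of 15, among them Hsd3b5 (-9.29 ± 1.45), Mup7 (-5.09 ± 1.38), Cyp4a12b (-3.72 ± 1.03) and Slco1a1 (-2.78 ± 0.72) (9 adjusted over the list alone; camera adjusted p = 0.000413, and adjusted p = 0.723 with an estimated correlation). Mup7 was not called without vehicle replicate 1 (-4.10) or 30 µg/kg replicate 1, 4 or 5 (-4.73 to -4.80). Cyp4a12b was called only where 30 µg/kg replicate 2, vehicle replicate 4 or 5 or a library of another dose was the 1 left out (-3.27 to -3.59 in the other 7 cases). Slco1a1 was not called without vehicle replicate 1 (-2.39). Without 30 µg/kg replicate 2 Slco1a1 had -4.39 and Cyp4a12b -5.85. In cholesterol synthesis 3 of 24 were higher, Mvk among them (5 adjusted over the list alone; camera adjusted p = 1.51e-06, and adjusted p = 0.723 with an estimated correlation). In the trend among the libraries labelled with TCDD this list was not called, with 2 of 24 rising and 6 falling (camera adjusted p = 0.176). Respiratory chain genes were lower in 3 of 20, Cycs, Cox7a2 and Cox6c (3 adjusted over the list alone; camera adjusted p = 0.00299, and adjusted p = 0.734 with an estimated correlation). Cox6c was not called without vehicle replicate 1 (-0.38).

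In all 17 of 43 lists were called at 30 µg/kg, and no list with an estimated correlation (lowest adjusted p = 0.265). The AhR battery had 1 called member of 14, the xanthine dehydrogenase gene Xdh at 0.96 ± 0.15 (2 adjusted over the list alone; camera adjusted p = 5.01e-07, and adjusted p = 0.529 with an estimated correlation). Also called were neutrophil markers (3 of 6 higher), stellate cell markers (1 of 16 higher), cell cycle (1 of 25 higher, Mcm3), recruited macrophage and monocyte markers (1 of 15 higher, 1 lower), fatty acid oxidation (2 of 25 lower) and PPARalpha targets (1 of 15 lower), with adjusted p between 0.723 and 0.798 with an estimated correlation. Outside the called lists, Pklr (-1.96 ± 0.46), Igfbp2 (-2.41 ± 0.55) and Apoa1 (-1.55 ± 0.38) were lower, and Igfbp3 (0.77 ± 0.18) and Hsd17b6 (1.21 ± 0.29) higher. Apoa1 was not called without vehicle replicate 1 (-1.31) or 3 (-1.30), nor Pklr without vehicle replicate 2 (-1.55). Mcm3 was not called without vehicle replicate 1 (0.83) or 3 (0.81). In the acute phase list, not called, 7 of 16 were higher, among them Saa2 (7.89 ± 1.46), Saa1 (6.70 ± 1.24), Orm3 (4.41 ± 0.98) and Saa3 (4.26 ± 0.90). Without the library labelled 30 µg/kg replicate 1 none of these 4 was called, at 1.33, 0.90, -0.56 and -0.37, and the neutrophil genes S100a9 and S100a8 went from 4.23 and 3.98 to -0.084 and -0.35 and were not called.

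At 10 µg/kg 213 genes were higher and 146 lower than in the libraries labelled vehicle, 359 in all (171 higher and 177 lower with upper-quartile scaling). The interferon-inducible GTPase gene Tgtp1 (2.20 ± 0.53), Acpp (2.15 ± 0.33) and Sult5a1 (2.03 ± 0.50) rose most among genes whose values did not overlap, and Stac3 (-1.77 ± 0.48), the protease inhibitor gene Serpine2 (-1.69 ± 0.28) and Rrm2, which supplies nucleotides for DNA synthesis (-1.57 ± 0.39), fell most. Lists called numbered 20 of 43, none of them with an estimated correlation (lowest adjusted p = 0.469), and 10 without vehicle replicate 4 or 5. Cholesterol synthesis genes were higher in 3 of 24 (7 adjusted over the list alone; camera adjusted p = 3.4e-11, and adjusted p = 0.469 with an estimated correlation), and sinusoidal endothelial cell markers in 3 of 13 (8 adjusted over the list alone; camera adjusted p = 1.79e-07, and adjusted p = 0.469 with an estimated correlation). In the trend among the libraries labelled with TCDD 2 cholesterol synthesis genes rose and 6 fell, Sc5d among the latter. Sc5d was uneven in the libraries labelled vehicle, at 507.5 ± 338 CPM against 545.9 ± 82.25 CPM at 10 µg/kg. Higher levels of this list against vehicle may thus rest on part of the vehicle libraries. Cell cycle genes were lower in 2 of 25 (13 adjusted over the list alone; camera adjusted p = 0.000932, and adjusted p = 0.662 with an estimated correlation). The cell cycle gene Mcm5 was uneven in the libraries labelled vehicle, at 6.68 ± 5.82 CPM against 4.95 ± 0.766 CPM at 10 µg/kg. The male-biased list was called up with a median of -0.08 (camera adjusted p = 0.0187, and adjusted p = 0.792 with an estimated correlation). Limma-voom with quality weights called 2467 genes, and edgeR called 111 higher and 58 lower without 10 µg/kg replicate 3 and 142 genes without replicate 5. Tgtp1 was not called without 10 µg/kg replicate 5 (1.48) or vehicle replicate 4 (1.98), nor Sult5a1 without 10 µg/kg replicate 3 (1.93). Stac3 was not called without 10 µg/kg replicate 1, 2, 3 or 5 or vehicle replicate 1 or 5 (-1.66 to -1.75). Rrm2 was not called without 10 µg/kg replicate 1, 3 or 5 (-1.45 to -1.62) or vehicle replicate 4 (-1.18).

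At 3 µg/kg 172 genes were higher and 279 lower, 451 in all. Ubd (2.98 ± 0.72), Tgtp1 (2.72 ± 0.54) and Mup12 (2.41 ± 0.59) rose most among genes whose values did not overlap, and Grhl1 (-2.69 ± 0.64), Kcnj8 (-2.67 ± 0.46) and Cgref1 (-2.54 ± 0.62) fell most. Lists called numbered 24 of 43, none of them with an estimated correlation (lowest adjusted p = 0.455), and 15 without vehicle replicate 4. Cell cycle genes were lower in 5 of 25 (18 adjusted over the list alone; camera adjusted p = 1.32e-07, and adjusted p = 0.455 with an estimated correlation), recruited macrophage and monocyte markers in 6 of 15 (9 adjusted over the list alone; camera adjusted p = 0.00159, and adjusted p = 0.458 with an estimated correlation) and stellate cell markers in 4 of 16 (11 adjusted over the list alone; camera adjusted p = 0.0001, and adjusted p = 0.458 with an estimated correlation). These 3 lists rose in the trend among the libraries labelled with TCDD. The libraries labelled vehicle were uneven in the 2 cell cycle genes named there. Mcm5 lay at 6.68 ± 5.82 CPM in them against 3.98 ± 0.853 CPM at 3 µg/kg, and Ccnb1 at 2.67 ± 3.74 against 0.324 ± 0.172 CPM. The lower levels at this dose may thus rest on part of the vehicle libraries. With vehicle replicates 4 and 5 both left out 14 lists were called. The following were called up with a negative median: the AhR battery with -0.33 (camera adjusted p = 0.000337, and adjusted p = 0.455 with an estimated correlation) and de novo lipogenesis with -0.01 (camera adjusted p = 0.0362, and adjusted p = 0.641 with an estimated correlation). The count was 133 and 229 without vehicle replicates 4 and 5, 769 to 842 without vehicle replicate 1, 2 or 3, 197 to 272 without 3 µg/kg replicate 1, 2, 3 or 4, and 735 by limma-voom with quality weights. Ubd was not called without 3 µg/kg replicate 5 (2.67) or vehicle replicate 4 (2.93), nor Mup12 without vehicle replicate 4 (2.14). Grhl1 was not called without vehicle replicate 4 (-2.46) or 5 (-2.08). Cgref1 was not called without vehicle replicate 4 or 5 or 3 µg/kg replicate 1 or 2 (-2.23 to -2.49).

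At the 4 lowest doses most called genes were lower than in the libraries labelled vehicle: 596 of 639 at 0.03 µg/kg, 612 of 675 at 0.1 µg/kg, 375 of 421 at 0.3 µg/kg and 370 of 457 at 1 µg/kg. AhR genes were among them at 0.03 µg/kg, where Cyp1b1 had a log2 fold change of -10.43 ± 1.67, Ahrr -8.14 ± 1.41, Tiparp -3.85 ± 0.70, Nqo1 -3.50 ± 0.60 and Cyp1a2 -1.98 ± 0.59 (edgeR adjusted p between 0.000816 and 0.0484). Cyp1a2 was not called without any of 31 of the 40 libraries, each left out alone (-1.38 to -2.22). These directions rest on the libraries labelled vehicle replicates 4 and 5: with both left out, chosen after their values were seen, 4, 8, 22 and 126 genes were called at the 4 doses, and Cyp1a1 had 6.54 at 0.03 µg/kg. With vehicle replicate 4 or 5 alone left out 70 to 142 genes were called at each of the 4 doses, and 959 to 1807 without vehicle replicate 1, 2 or 3. The counts were 328 to 394 without 0.03 µg/kg replicate 1, 3, 4 or 5, 296 to 391 without 0.1 µg/kg replicate 2, 3, 4 or 5, 171 to 226 without any 1 library of 0.3 µg/kg, and 224 to 282 without 1 µg/kg replicate 1, 3, 4 or 5.

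The genes named next had values that did not overlap between the 5 libraries of the dose and the 5 labelled vehicle. At 0.03 µg/kg Cyp2a4 (-6.34 ± 1.09), Myom1 (-4.74 ± 0.70) and Rcan3 (-3.90 ± 0.68) fell most, and Asic5 (0.86 ± 0.22), Arhgap26 (0.76 ± 0.22) and Zbtb48 (0.68 ± 0.20) rose most. At 0.1 µg/kg Mapk13 (-3.38 ± 0.92), Cd63 (-2.74 ± 0.54) and Grhl1 (-2.63 ± 0.63) fell most, and Ccdc30 (0.96 ± 0.28), Insc (0.90 ± 0.27) and Lcmt1 (0.79 ± 0.15) rose most. At 0.3 µg/kg the proliferation marker gene Mki67 (-3.17 ± 0.68), Armcx4 (-2.15 ± 0.52) and the glutathione transferase gene Gstm2 (-2.08 ± 0.38) fell most, and Mup12 (2.21 ± 0.58), Cyp2g1 (1.85 ± 0.51) and Ccdc30 (1.04 ± 0.28) rose most. At 1 µg/kg the DNA replication gene Gins2 (-4.09 ± 0.77), Grhl1 (-3.41 ± 0.67) and Ak1 (-3.40 ± 0.90) fell most, and Mup12 (2.80 ± 0.59), Mup1 (2.33 ± 0.59) and Cyp2g1 (2.18 ± 0.51) rose most.

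Many of these calls ended when 1 library was left out. At 0.03 µg/kg Asic5 was not called without vehicle replicate 4 (0.72) or 5 (0.83). Arhgap26 (0.55 to 0.80) and Zbtb48 (0.51 to 0.72) were not called without either of these or any library of the dose, nor Zbtb48 without 0.1 µg/kg replicate 3 (0.67). At 0.1 µg/kg Grhl1 was not called without vehicle replicate 4 (-2.40) or 5 (-2.01). The same vehicle libraries ended the calls of Insc (0.69 to 0.96), as did any library of the dose, of Ccdc30 (0.73 to 0.99), as did replicates 1 to 4 of the dose, and of Mapk13 (-2.93 to -3.79), as did replicates 2 to 5. At 0.3 µg/kg Mki67 was not called without vehicle replicate 4 (-2.40). Ccdc30 (0.80 to 1.07) and Cyp2g1 (1.65 to 1.94) were not called without vehicle replicate 4 or 5 or any library of the dose. Mup12 was not called without either vehicle library or 0.3 µg/kg replicate 2, 3 or 5 (1.86 to 2.19), nor Armcx4 without either or replicate 5 (-1.42 to -2.08). At 1 µg/kg Mup1 (2.03 and 1.99) and Cyp2g1 (2.00 and 1.98) were not called without vehicle replicates 4 and 5, each left out alone. Ak1 was not called without vehicle replicate 2 (-2.38) or 4 (-3.44) or 1 µg/kg replicate 1, 3, 4 or 5 (-3.11 to -3.54).

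**Figure D4:**
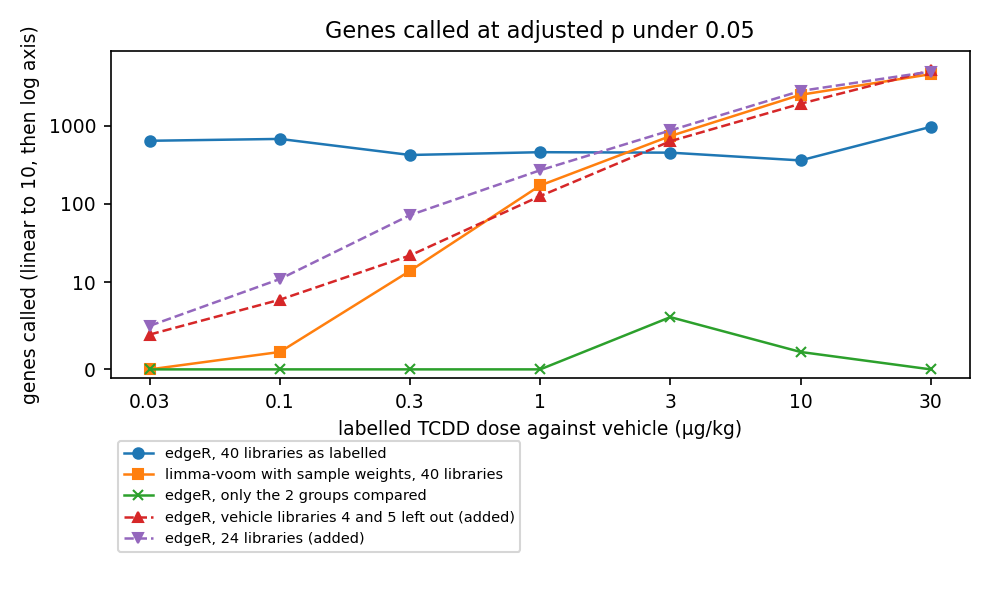
Genes called at each labelled TCDD dose in µg/kg against the libraries labelled vehicle under 5 fits, on an axis that is linear to 10 and logarithmic above; dashed lines are alternatives added after the data were seen. With all 40 libraries as labelled edgeR called between 359 and 962 genes, and limma-voom with sample quality weights between 0 (685 at an unadjusted p under 0.05) and 4519.

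Contrasts between adjacent high doses hold no vehicle library. At 30 against 10 µg/kg 56 genes were higher and 27 lower. A1bg (5.95 ± 1.31), the interferon lambda receptor gene Ifnlr1 (4.91 ± 1.18) and the myosin gene Myo7b (3.80 ± 0.80) rose most, and Mup1 (-3.35 ± 0.67), Mup12 (-2.89 ± 0.62) and Ppp1r1b (-2.57 ± 0.63) fell most. The count of 83 rested on single libraries: by edgeR it was 0 without 10 µg/kg replicate 1, 2, 3 or 5 or 30 µg/kg replicate 1 (1976 to 2893 at an unadjusted p under 0.05), and 993, 290 and 37 without 30 µg/kg replicates 2, 3 and 4. It was 375, 154, 161 and 147 without vehicle replicates 4, 5, 1 and 3, and 51 to 55 without any of 17 libraries of the 5 lower doses. A1bg (5.29 to 6.47), Myo7b (3.51 to 5.11) and Mup12 (-2.58 to -3.11) were not called without 10 µg/kg replicate 1, 2, 3 or 5 or 30 µg/kg replicate 1 or 4. Mup1 was not called without these except the last (-3.004 to -3.56). Ifnlr1 was not called without any of 29 libraries, each left out alone (4.50 to 5.87), nor Ppp1r1b without any of 31 (-2.15 to -2.73). With all libraries DESeq2 called 409 genes and limma-voom with quality weights 1269. At 10 against 3 µg/kg edgeR called 0 genes, with 1007 at an unadjusted p under 0.05; DESeq2 called 1, limma-voom with quality weights 25, and limma on the deposited normalized values called 0 (1371 at an unadjusted p under 0.05). Over the 40 libraries 4416 genes differed between any of the 8 groups by edgeR, and 1694 rose and 1501 fell with the dose rank. Without vehicle replicate 4 the trend called 5143 genes in place of 3195.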

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

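The tests of mislabelling, exposure, mixing, a few genes taking most counts and library size were chosen after the result was seen; the test of cell type markers in the library labelled 30 µg/kg replicate 1 was written before its result.

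In 710 groups of 5 libraries (112 of AhR genes, Alb and library measures and 598 of other named genes), 60 held a library whose gap to its nearest neighbour exceeded the 95% critical value of Dixon's ratio. Chance meets this rule in about 1 in 20 groups. The library labelled 30 µg/kg replicate 1 accounted for 22 of the 60 and replicate 2 for 5.

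The libraries labelled vehicle replicates 4 and 5 carried AhR gene levels within or above the range of the libraries labelled 30 µg/kg, with Nqo1 at 233 and 171 CPM against 38.4 to 88.1 CPM. A mixture with RNA of another mouse cannot exceed its source. The lower of their 2 Cyp1b1 values lay 2.57 SD above the mean of the 5 libraries labelled 30 µg/kg. This argues against a mixture with RNA of the mean level of these 5. A source with a higher level is not known from the labels and was not tested. Wrong labels stay open: over 1000 variable genes outside the AhR list, 12 of the 16 libraries out of step with the inferred layout were nearer to its dose than to their own label, where the bound set for wrong labels was over 12, and replicates 4 and 5 lay at 0.98 and 0.73 from the layout's dose against 2.64 and 2.45 from the other vehicle libraries. The margin was small in 3 of the 12. These were 0.03 µg/kg replicate 3 (0.485 against 0.487 from its label, and nearest of all to 0.1 µg/kg) and 3 µg/kg replicates 1 (0.481 against 0.494) and 2 (0.567 against 0.573). The exceptions were 30 µg/kg replicate 1 and, by small margins, 0.1 µg/kg replicates 3 (0.529 against 0.496 from its label) and 4 (0.617 against 0.597) and 0.3 µg/kg replicate 3 (0.57 against 0.523). The same distances were not taken for the libraries in step. How often a library with the right label is nearer to another dose is thus not known, and the tally cannot decide for or against wrong labels. For vehicle replicates 4 and 5 true exposure of these mice predicts the same values as wrong labels. In these libraries they cannot be told apart without records of the mice. Exposure of these mice makes no prediction for the other libraries out of step. Cyp1a1 lay at 215 and 209 CPM in 0.1 µg/kg replicates 3 and 4, against 214 to 266 CPM in the libraries in step labelled 0.03 µg/kg. Exposure of the 2 vehicle mice alone does not account for such values, which led to the inferred layout and are no independent evidence.

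In the library labelled 30 µg/kg replicate 1 Alb lay at 26173 CPM, against 61359 to 84807 CPM in the other 4 of that label; it was also low in vehicle replicates 4 and 5, at 35725 and 45718 CPM against 81190 to 88723 in the other 3 labelled vehicle. A loss of hepatocytes alone would raise the markers of every other cell type, though on the scale used less for genes near 0 CPM. The medians moved apart instead, and some lay below 0. Skeletal muscle and mesothelium markers lay at -0.47 on the log2 scale (-0.94 to 0.24 over 6 genes) and endothelial markers at -0.19 (-1.06 to 0.79). Kupffer cell markers lay at 2.08 (1.49 to 5.64), neutrophil markers at 3.99 (2.53 to 6.09) and hepatocyte markers at -0.34 (-1.48 to 1.37). These values argue against a loss of hepatocytes alone. Added cells of only some types would also lower the hepatocyte share, and this test cannot exclude that. The 10 most abundant genes other than Alb took 20.1% of the counts (13.4% to 15.9% in the other 4), but a few genes taking most counts would lower every other gene as much as Alb (-1.43 on the log2 scale before scaling), and the median of 7762 other genes lay at -0.031 (SD 0.61), which argues against it as the whole cause. Library size is argued against by the 10 libraries with at least as many counts in genes (20.27 M to 29.48 M), where Alb lay at 69870 to 93128 CPM, further above this library than the SD of the other 4 (9786 CPM), although vehicle replicate 5, at 45718 CPM, held nearly as many (20.24 M). The labels give this library the same dose as the other 4, so no biological explanation was tested.

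In the same library the acute phase genes stood above the other 4: Saa1 at 15020 CPM (29.4 to 73.0 in the others), Saa2 at 14790 CPM (14.9 to 43.5), Saa3 at 534.7 CPM and Orm3 at 155.7 CPM. Neutrophil genes were S100a9 at 192 CPM, S100a8 at 116.7 CPM, Mmp8 at 29.6 CPM and Mmp9 at 24.2 CPM. Macrophage and Kupffer cell genes were Lyz2 at 561 CPM, Csf1r at 404 CPM (64.6 to 91.6 in the others), Clec4f at 284 CPM, Adgre1 at 119 CPM, Cd163 at 47.5 CPM and Cd68 at 40.9 CPM. Plasma cell genes were Igkc at 75.8 CPM and Jchain at 18.8 CPM. Slc1a2 lay at 487 CPM, Trpm2 at 41.1 CPM, Rassf4 at 40.8 CPM and P2rx7 at 14.7 CPM. Below the other 4 lay Hsd17b6 at 703 CPM (963 to 1011) and the endothelial gene Kdr at 45.5 CPM (64.4 to 72.0).

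In the library labelled 30 µg/kg replicate 2 male-biased genes stood above the other 4: Serpina1e at 710.2 CPM (6.55 to 18.6 in the others), Slco1a1 at 132.4 CPM (4.90 to 16.5), Cyp4a12b at 24.9 CPM, Mup7 at 2.27 CPM and Hsd3b5 at 0.954 CPM. In 30 µg/kg replicate 3 Smcp lay at 3.74 CPM, above the others, and Grik5 at 3.98 CPM, below them.

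Among measures of whole libraries, 0.03 µg/kg replicate 1 had 31.7% unmapped reads (95% Wilson interval 31.71 to 31.74) against 3.70% to 4.47% in the others of its label, and 4.46% multimapping reads (4.45 to 4.47). Reads in no gene made up 9.34% (9.33 to 9.35) in 0.03 µg/kg replicate 3 and 9.37% (9.36 to 9.38) in 0.1 µg/kg replicate 1.

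Among the AhR genes, Ahr lay at 75.5 CPM in vehicle replicate 5 (44.6 to 51.6 in the others of its label), Cyp1a1 at 5527 CPM in 3 µg/kg replicate 1 (6638 to 7088) and Cyp1a2 at 20040 CPM in 10 µg/kg replicate 1 (21190 to 21590). In the libraries labelled vehicle, Mylpf lay at 13.5 CPM and Ak1 at 4.30 CPM in replicate 2, and Cidec at 0.894 CPM in replicate 5, below the others.

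At 0.03 µg/kg Apoe lay at 29160 CPM and Igkc at 5.24 CPM in replicate 2, and Gpx2 at 0.0527 CPM in replicate 5. At 0.1 µg/kg Cycs lay at 106.7 CPM in replicate 2, H2-Ab1 at 18.0 CPM in replicate 3, Il2rb at 2.53 CPM and Mmp8 at 0.140 CPM in replicate 4, and Gpx2 at 0.056 CPM in replicate 5. At 0.3 µg/kg Ambp lay at 2798 CPM in replicate 1, Csf1r at 63.2 CPM and, below the others, Gstm2 at 58.0 CPM in replicate 3, Col1a1 at 20.9 CPM in replicate 4, and Gpx2 at 0.0448 CPM in replicate 5. The other 4 libraries held no count of Gpx2 at these 3 doses.

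At 1 µg/kg Mmp8 lay at 0.0564 CPM in replicate 1, with no count in the others, Ccnb1 at 0.304 CPM in replicate 2 and Mcm5 at 2.72 CPM in replicate 4. At 3 µg/kg Cycs lay at 83.1 CPM and Sult2a1 at 0.679 CPM in replicate 4, and Gzmb at 1.92 CPM in replicate 5. At 10 µg/kg Scp2 lay at 3103 CPM in replicate 2 and Tgtp1 at 20.76 CPM in replicate 5.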

How the results depend on the processing

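The fits of 24 libraries, without vehicle replicates 4 and 5, and the refits of the trend without vehicle were chosen after seeing the data; the AhR genes, whose values led to the first pair, are not independent evidence in them. No paired analysis was possible because the labels give no replicate numbers that pair mice across groups. Libraries held 15311574 to 29476550 counts, and depth limits genes near 0 counts, such as Gpx2 at the lowest doses.

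DESeq2 size factors, upper-quartile scaling and a filter of 1 CPM in 5 libraries left each count of called genes within 1.5 times its value as labelled. Of 168 comparisons of named genes, 134 were called as labelled. Of those with a value, none changed direction under these settings (165 with the filter of 1 CPM), with the DESeq2 test, without a filter, with only the 2 groups compared (158), with the title-number covariate or on the normalized table. Calls were lost in 123 with only the 2 groups compared, 66 on the normalized table, 42 with limma-voom, 38 in the 24 libraries, 35 without vehicle replicates 4 and 5, 11 without a filter, 8 with DESeq2, 5 with the covariate and 1 with upper-quartile scaling. Where a cause is not named below, the cause was not tested.

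The trend without vehicle called 6817 genes in place of 3195 with vehicle. It called 6034 with limma-voom, of which 5655 were also among the 6817, 6823 with DESeq2 size factors, 6776 with upper-quartile scaling, 6986 with the covariate and 8452 without a filter. In the 21 libraries in step it called 5828. Without single libraries it called 6277 to 6966.

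With sample quality weights limma-voom called 0 (685 at an unadjusted p under 0.05, against 3319 by edgeR), 2, 14, 172, 735, 2467 and 4519 genes at 0.03, 0.1, 0.3, 1, 3, 10 and 30 µg/kg, 25 at 10 against 3 µg/kg, 1269 at 30 against 10 µg/kg and 6629 for the trend. Directions turned upward, in log2, for Cyp1a2 (0.86, 2.25 and 3.14 at 0.03, 0.1 and 0.3 µg/kg), Nqo1 (0.20, 0.55, 1.06, 1.43, 1.68 and 2.75 from 0.1 to 30 µg/kg), Ahrr (1.28 at 0.3 µg/kg), Cyp1b1 (1.62, 7.62 and 8.76 at 0.3, 3 and 10 µg/kg) and Tiparp (0.33 and 2.78 at 1 and 10 µg/kg). Orm3 turned to -0.31 at 30 µg/kg.

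With only the 2 groups compared, edgeR called 0 genes at 0.03, 0.1, 0.3, 1 and 30 µg/kg (1372, 1455, 1198, 1438 and 1473 at an unadjusted p under 0.05), 6 at 3 µg/kg, 2 at 10 µg/kg and 0 at 30 against 10 µg/kg (2602 unadjusted; DESeq2 in all groups called 409), and 15 lists at 3 µg/kg. These fits hold 10 libraries in place of 40. The DESeq2 test called 654, 734, 696 and 607 genes at 0.3, 1, 3 and 10 µg/kg, 1 at 10 against 3 µg/kg and 409 at 30 against 10 µg/kg. With the title-number covariate 1115 and 1154 genes were called at 0.03 and 0.1 µg/kg, 1 at 10 against 3 µg/kg and 216 at 30 against 10 µg/kg. On the normalized table limma called 0 genes at 0.03, 0.1 and 0.3 µg/kg (4344, 4364 and 3678 at an unadjusted p under 0.05), 59 at 1 µg/kg, 206 at 3 µg/kg and 3 at 30 against 10 µg/kg. A log2 fold change of at least 1 left 237, 111 and 401 genes at 3, 10 and 30 µg/kg, since it removes smaller changes. Without a filter 235 were called at 10 µg/kg, with 31966 genes tested in place of 15610.

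Of the lists, 0 were called at 30, 10 and 3 µg/kg by camera with an estimated correlation. Fry called 6, 1 and 0 at these doses. In the trend without vehicle camera called 27 of 43 lists at the preset correlation and 1 with an estimated correlation.

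In the 24 libraries in step 5, 11, 72, 269, 866, 2763 and 4880 genes were called at the 7 doses in ascending order, 65 at 10 against 3 µg/kg, 682 at 30 against 10 µg/kg and 6152 for the trend. Of the calls as labelled 3, 3, 15, 41, 115, 226 and 815 were among them at the 7 doses. Within these libraries the other tools, scaling, filter and covariate gave 3 to 238 genes at 0.03 µg/kg and 3480 to 5181 at 30 µg/kg. Directions turned upward for Cyp1a1 (7.28 and 9.94 at 0.03 and 0.1 µg/kg), Cyp1a2 (2.03, 2.80 and 3.71 at 0.03, 0.1 and 0.3 µg/kg), Cyp1b1 (0.22, 0.78, 3.55, 7.60, 8.91 and 10.02 from 0.03 to 10 µg/kg), Nqo1 (0.051, 0.69, 1.01, 1.52, 1.81, 2.10 and 3.36 from 0.03 to 30 µg/kg), Ahrr (3.12, 5.66 and 6.90 at 0.3, 1 and 3 µg/kg) and Tiparp (0.22, 1.00, 2.699 and 3.57 at 0.1, 1, 3 and 10 µg/kg). Jchain turned to -0.19 at 30 µg/kg.

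Without vehicle replicates 4 and 5, 4, 8, 22, 126, 1897 and 5043 genes were called at 0.03, 0.1, 0.3, 1, 10 and 30 µg/kg, 4 at 10 against 3 µg/kg, 1745 at 30 against 10 µg/kg and 7172 for the trend, and 14 and 27 lists at 3 and 30 µg/kg. Directions turned upward for Cyp1a1 (6.54 and 9.33 at 0.03 and 0.1 µg/kg), Cyp1a2 (1.54, 2.55 and 3.44 at 0.03, 0.1 and 0.3 µg/kg), Cyp1b1 (0.20, 0.57, 2.93, 6.93, 8.50 and 9.54 from 0.03 to 10 µg/kg), Nqo1 (0.57, 0.86, 1.36, 1.77, 1.99 and 3.03 from 0.1 to 30 µg/kg), Ahrr (2.45, 5.01 and 6.50 at 0.3, 1 and 3 µg/kg) and Tiparp (0.70, 2.23 and 3.17 at 1, 3 and 10 µg/kg).

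Leaving out 1 library at a time, the count lay between 103 (without vehicle replicate 4) and 1785 (without vehicle replicate 1) at 0.03 µg/kg, 85 and 1807 (vehicle replicates 4 and 3) at 0.1 µg/kg, 70 and 1141 (vehicle replicates 4 and 3) at 0.3 µg/kg, 76 and 1111 (vehicle replicates 4 and 3) at 1 µg/kg and 133 and 842 (vehicle replicates 4 and 1) at 3 µg/kg. It lay between 142 and 520 (10 µg/kg replicate 5 and 30 µg/kg replicate 1) at 10 µg/kg and 417 and 2257 (vehicle replicates 3 and 4) at 30 µg/kg. At 10 against 3 µg/kg it was 0 or 1, at 30 against 10 µg/kg 0 to 993, and for the trend 2490 to 5143. Lists numbered 10 to 23 at 10 µg/kg (vehicle replicates 4 and 1) and 15 to 27 at 3 µg/kg (vehicle replicate 4 and 3 µg/kg replicate 3). At 30 µg/kg Orm3 ranged from -0.56 to 4.74, Saa3 from -0.37 to 4.76, S100a9 from -0.084 to 4.81 and S100a8 from -0.35 to 4.56, each lowest without 30 µg/kg replicate 1.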

Other observations

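The genes of the first pair of paragraphs and the test of other splits at 30 µg/kg against vehicle were chosen after the result was seen.

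Among the 35 libraries labelled with a TCDD dose, isozymes of glycolysis moved apart. Pkm, the pyruvate kinase of muscle and dividing cells, rose by 0.38 ± 0.03 (SE) on the log2 scale per dose step (edgeR adjusted p = 2.09e-13), while Pklr, that of liver, fell by 0.43 per step. Hk1 and Hk2, hexokinases of tissues other than hepatocytes, rose by 0.19 ± 0.03 and 0.36 ± 0.05. In the same libraries Kupffer cell (12 of 13), stellate cell (15 of 16) and recruited macrophage markers (14 of 15) rose and hepatocyte markers (7 of 12) fell. Among lipid uptake and storage genes, the lipases Lpl (0.27 ± 0.03) and Mgll (0.26 ± 0.02) and the lipoprotein receptor gene Vldlr (0.20 ± 0.04) rose, and the droplet protein genes Cidec (-0.19 ± 0.05) and Plin5 (-0.09 ± 0.03) fell. Neither list was called (camera adjusted p = 0.497 and 0.603), and each of these genes was called without any 1 of the 35 libraries.

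Targets of PPARalpha and of CAR and PXR went both ways. Of the former, the fasting hormone gene Fgf21 (0.64 ± 0.13) and Pdk4 (0.23 ± 0.04) rose, and Cyp4a14 (-0.43 ± 0.10) and Ppara itself (-0.11 ± 0.02) fell. Of the latter, Cyp2b13 (1.25 ± 0.14), Gstm3 (0.47 ± 0.05) and Cyp2b10 (0.40 ± 0.07) rose, and Cyp3a13 (-0.16 ± 0.03) and Cyp3a25 (-0.14 ± 0.03) fell. Cyp2b13 is also in the female-biased list. The periportal genes Sds (-0.30 ± 0.06), Hal (-0.23 ± 0.04) and Gls2 (-0.18 ± 0.02) fell and Hsd17b6 (0.50 ± 0.03) rose, and of the pericentral genes Slc1a2 rose (0.27 ± 0.02) and Glul fell (-0.11 ± 0.02). Acta1, the actin gene of skeletal muscle, rose by 2.19 ± 0.20 per step, and by 1.65 to 2.85 without any 1 library, a slope that depends on counts near 0: its mean was at most 0.149 CPM up to 3 µg/kg and 17.9 ± 20.1 CPM at 30 µg/kg. In the 24 libraries in step Acta1 had -0.28 ± 1.07 at 30 µg/kg against vehicle (edgeR adjusted p = 0.876). These 4 lists and that of skeletal muscle and mesothelium were not called (camera adjusted p between 0.157 and 0.282).

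Other splits of the libraries into groups of the same sizes gave counts as large as those against the libraries labelled vehicle, so chance could not be excluded there. As many genes as called were found in 31 of 100 splits at 0.03 µg/kg (639 called, highest other 1356), 29 at 0.1 µg/kg (675, highest 1127), 42 at 0.3 µg/kg (421, highest 1514), 20 at 1 µg/kg (457, highest 1628), 13 at 3 µg/kg (451, highest 2151), 12 at 10 µg/kg (359, highest 4285) and 16 at 30 µg/kg (962, highest 5507). The highest splits lay above the real count at each dose, and several times above it from 0.3 µg/kg up. They kept vehicle replicates 4 and 5 together and point to a structure of the samples. With the pair parted the highest was 3, 0, 0, 0, 17, 52 and 1303 genes by edgeR at the 7 doses in ascending order. As many lists as called were found in 58 of 100 splits at 30 µg/kg (17 called, highest 33), 42 at 10 µg/kg (20, highest 31) and 34 at 3 µg/kg (24, highest 31).

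For the comparisons that draw on all doses or hold no vehicle library the splits gave other results. The real split alone reached its count for the trend without vehicle (1 of 100 splits, 6817 genes, highest other 120), the trend with vehicle (1 of 100, 3195, highest other 332) and any difference between the 8 groups (1 of 40, 4416, highest other 275), so chance was excluded. At 30 against 10 µg/kg 2 of 100 splits reached 83 genes, the real split among them, which met the bound set in advance against chance. But the highest other split called 282, several times the real count, which points to a structure of the samples. The real count also rested on single libraries, so this share alone does not exclude chance. By edgeR the real count was 0 without 10 µg/kg replicate 1, 2, 3 or 5 or 30 µg/kg replicate 1 (1976 to 2893 at an unadjusted p under 0.05; with all libraries DESeq2 called 409 and limma-voom with quality weights 1269). At 10 against 3 µg/kg edgeR called 0 genes (1007 at an unadjusted p under 0.05; 1 by DESeq2 and 25 by limma-voom), which all 100 splits reached (highest other 2).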
